A study of Mus musculus with 4 samples.

How the data were processed

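Gene expression was measured on 4 whole-transcript Affymetrix mouse arrays, 1 for each of 4 groups by the labels: T cells of the colon lamina propria, intraepithelial lymphocytes (IEL, the lymphocytes that lie between the epithelial cells of the gut) of the small intestine, IEL of the colon, and colon IEL of mice that had been given antibiotics and then recolonized with bacteria. Per the labels, the mice were C57Bl/6 animals of 8 to 10 weeks, 10 mice (5 male and 5 female) went into a pool, and T cells were enriched with magnetic negative selection to which an antibody against EpCAM, a surface protein of epithelial cells, had been added. Antibiotics were given in the drinking water for 7 days and recolonization lasted 7 days; the labels describe the latter both as co-housing with littermates and as transfer of used bedding. The labels leave open whether 10 mice were pooled per array or over the series, and whether arrays shared mice.

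The deposited values are on a log2 scale and were made with Affymetrix Expression Console, per the submitters' processing notes; its version, the summarization method and the normalization are not given in the sources used here. Differences were therefore taken for the same gene, or the same probe set, between arrays. The value table held 41345 probe sets. Of these, 23521 listed 1 gene symbol, 1814 listed several and 16010 were not in the platform's gene table used here. Gene IDs of 23328 probe sets matched a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed updating. Probe sets with several symbols named no gene. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 22180 genes, 1082 of them with more than 1 probe set. No build is named for the probe sets, so no coordinates are printed.

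Each comparison was the difference of log2 levels between a pair of arrays. A gene entered the counts when its level on the brighter array of the pair was at or above the 50th percentile of all genes on that array, and was counted as higher or lower at a difference of 2-fold or more. With 1 array per group no test is possible, no p-value is given, and no difference has a replicate check. The number of arrays limits the precision. As yardsticks within a comparison, the spread of the log2 differences was taken over cytosolic ribosomal protein genes, over reference genes, and between the probe sets of genes that have 2 of them. For each gene list with at least 5 measured members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins; its percentile describes these arrays only. A list is called outside the range of random lists when it lies below the 2.5th or above the 97.5th percentile.

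The 45 gene lists, the comparisons, the level floor, the fold threshold and the rule for naming genes were fixed before the data were examined. The lists held 625 distinct genes, of which 549 were measured. Genes are named when they are among the 8 with the largest difference in either direction above the level floor (leaving out antigen receptor segments, unnamed genes, small RNAs and chemoreceptors), when they are among the genes named in any case (including Cd8a, Cd8b1, Cd4, Trdc, Itgae, Ccr9, Foxp3, Gzmb, Il6, Epcam and Jchain), or when they are among the 4 members of a described list with the largest difference. Other genes are named in the text as chosen after their values were seen. Trdc, Lck and Tcf7 had no probe set with a single symbol in the gene table used here and were not analysed here, and some other genes are not reported here.

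The alternatives were a level floor at the 25th or 75th percentile or none, a threshold of 1.5-fold or 3-fold, the mean of a gene's probe sets, quantile normalization, centring on the median of genes above the floor, and a lowess correction of the difference against mean level with a span of 0.3. An alternative pseudocount had been listed for linear values and was not run, since the values were on the log2 scale. Use of the recolonized array in place of the unmanipulated colon IEL array, and counts over only those genes that lay under the median level of the array labelled lamina propria T cells, were added after seeing the data. The steps that compute differences, counts and list medians were tested on simulated data for 22180 genes with an assumed noise SD of 0.3 per array. Planted log2 differences of 3.0 were recovered in 100% of genes in each of the 3 comparisons. Planted higher levels by 1.5 were recovered in 86% of genes for colon IEL against the array labelled lamina propria T cells, 76% for colon against small intestinal IEL and 86% for recolonized against unmanipulated colon IEL. Planted lower levels by 1.5 were recovered in 90%, 94% and 84% in the same order. Both directions were planted alike in a single random draw per comparison, so these gaps are not read as a bias towards either direction. Differences were planted only in a small set of genes brighter than the level floor, so dim genes were not tested. The assumed noise, also when taken over a difference of arrays, is smaller than each yardstick SD given below. The recovered shares therefore do not give the recovery on these arrays. The share of unchanged genes that passed is not reported here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.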

Results

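The series compared transcript levels between samples that the labels describe as T cells of different gut compartments. Colon IEL were set against the array labelled lamina propria T cells, against IEL of the small intestine, and against colon IEL of mice that had been treated with antibiotics and recolonized. Each group was 1 array made from pooled mice, so differences are given as log2 values without error or test. The median gene level was 2.18 on the array labelled lamina propria T cells, 2.24 on the small intestinal IEL array, 2.41 on the colon IEL array and 2.39 on the recolonized array. The spread of gene levels was narrower on both colon IEL arrays, with an SD of 1.23 for colon IEL and 1.35 for recolonized colon IEL against 1.81 and 1.67 for the array labelled lamina propria T cells and the small intestinal IEL array. The number of genes at a log2 level of 6 or more was 498 for colon IEL, 677 for recolonized colon IEL, 1377 for small intestinal IEL and 1790 for the array labelled lamina propria T cells.

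Marker genes were first set against the labels. The T cell receptor signalling genes, which include the CD3 chains and CD45 (Ptprc), had median levels of 5.32 on the small intestinal IEL array, 5.13 on the colon IEL array and 6.28 on the recolonized array, but 2.41 on the array labelled lamina propria T cells. Cd3e, a chain of the T cell receptor complex, was at 9.49, 9.17 and 9.43 on the 3 IEL arrays and at 3.72 on the array labelled lamina propria T cells. On that array the pan-epithelial markers had a median level of 8.51, the colonocyte markers 8.69 and the goblet cell markers 9.16. Epcam was at 9.20, the goblet cell mucin Muc2 at 11.55 and Car1, a carbonic anhydrase of colonocytes and red cells, at 11.53. Its content therefore went against its label, and it is called the array labelled lamina propria T cells throughout. The small intestinal IEL array also carried epithelial transcripts, with median levels of 9.25 for enterocyte markers and 9.20 for Paneth cell markers, and B cell markers at a median of 5.97. Stromal markers had median levels of 4.93 on the colon IEL array and 4.28 on the recolonized array. On the small intestinal IEL array and the array labelled lamina propria T cells they were at 2.99 and 2.89.

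**Figure D1:**
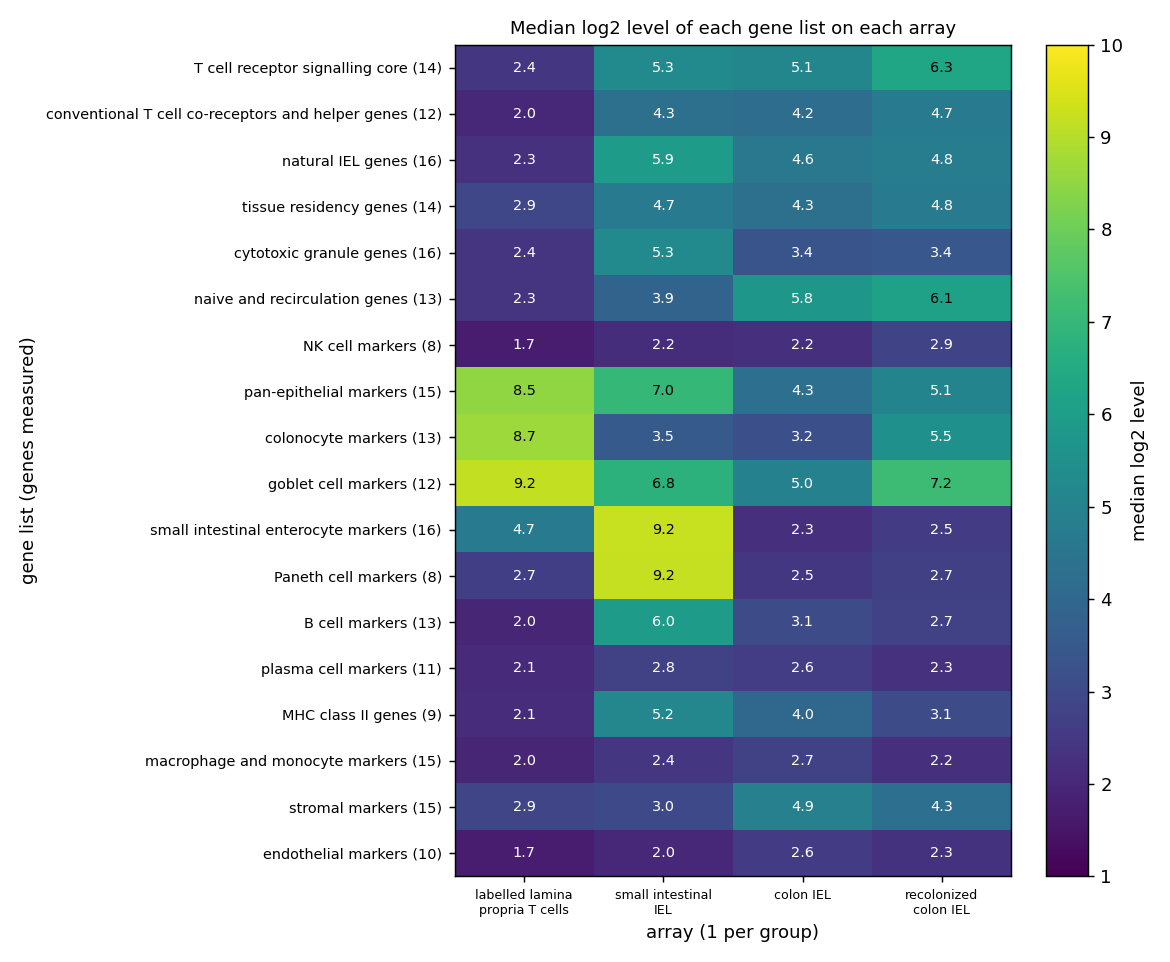
Median log2 level (colour and printed value) of 18 gene lists (rows, with the number of genes measured) on each of the 4 arrays (columns, 1 array per group). T cell receptor signalling genes have a median of 2.41 on the array labelled lamina propria T cells and between 5.13 and 6.28 on the IEL arrays, while colonocyte markers are at 8.69 on the former.

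Sex-linked genes differed between arrays. The labels name a pool of 5 male and 5 female mice, without settling whether this holds per array or over the series. Xist, transcribed from the inactive X chromosome, was at 1.86 on the array labelled lamina propria T cells, 5.70 on the small intestinal IEL array, 4.08 on the colon IEL array and 5.94 on the recolonized array. The Y-linked gene Eif2s3y was at 5.46, 4.67, 2.64 and 1.95 in the same order, and Uty at 4.85, 3.56, 2.20 and 1.86. The colon IEL array of unmanipulated mice also carried genes of red cells. Slc4a1, the band 3 anion exchanger of red cells, was at 7.93 there and between 2.32 and 2.64 on the other arrays, and Fech, the last enzyme of haem synthesis, was at 9.56 against 4.52 to 5.60. Isg20 was at 8.82 and the interferon-inducible Rsad2 at 8.36 on the same array, against 4.40 and 3.41 on the recolonized array.

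**Figure D2:**
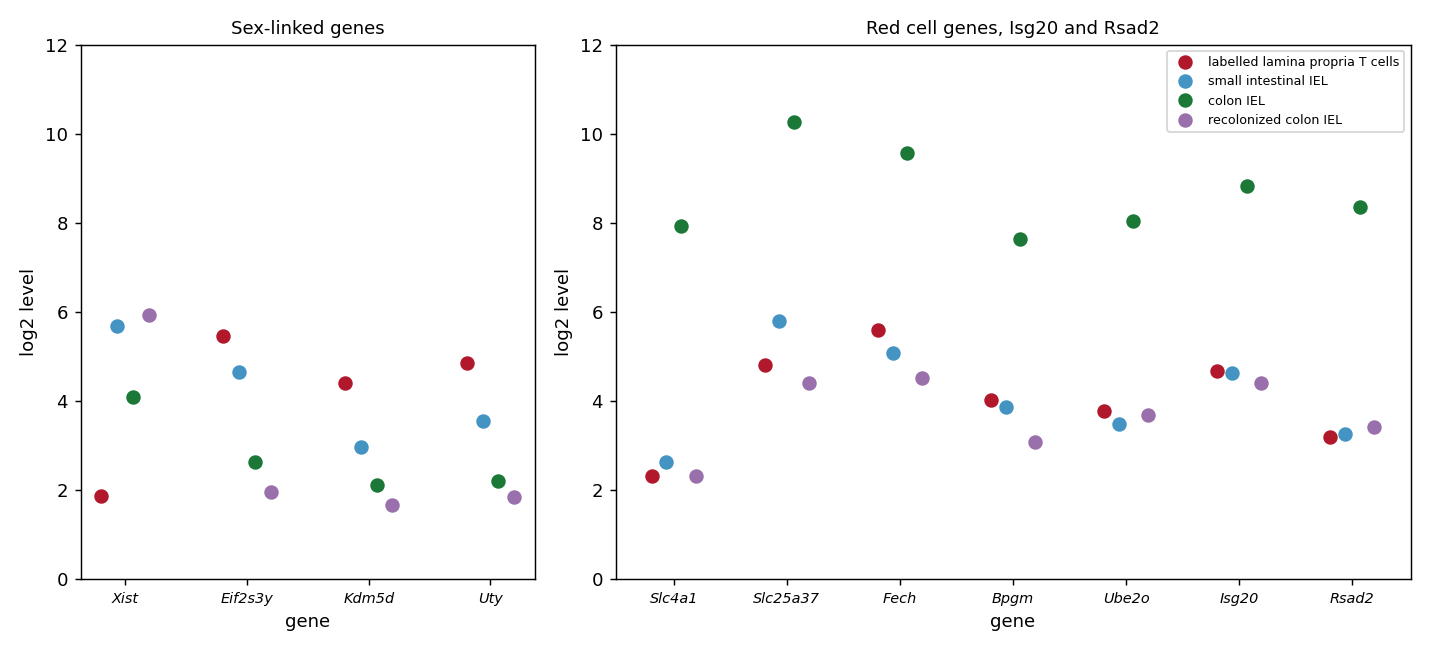
Log2 level (vertical axes) of 4 sex-linked genes (left) and of 5 genes of red cells with Isg20 and Rsad2 (right); each point is 1 array, coloured by group. Xist is at 1.86 on the array labelled lamina propria T cells and 5.94 on the recolonized array, and Slc4a1 is at 7.93 on the colon IEL array and at most 2.64 on the others.

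Colon IEL were compared with the array labelled lamina propria T cells to ask what sets lymphocytes of the epithelium apart from those beneath it. The content of the latter went against its label, so the directions below separate colon IEL from an array rich in colonic epithelial transcripts. Several T cell lists were higher in colon IEL and several epithelial lists lower. Others lay inside the range of random lists: gamma delta T cell genes (73.9th percentile), Th17 and type 3 genes (79.0th), Paneth cell markers (40.3rd), enteroendocrine and tuft cell markers (54.2nd) and butyrophilin-like genes (12.9th). The median difference of the T cell receptor signalling genes was 2.83, above all 10000 random lists. Of its 13 members above the level floor, 12 were at least 2-fold higher, among them Ptprc at 8.71 against 3.09 and Cd3g at 8.03 against 2.61. The naive and recirculation genes had a median difference of 2.64, with 11 of 13 members at least 2-fold higher. It was led by the interleukin-7 receptor Il7r at 7.71 against 1.52 and the transcription factor Lef1 at 7.14 against 2.37. The natural IEL genes had a median difference of 2.05, with 12 of 13 members at least 2-fold higher, including Cd7, Il2rb and Cd8a with differences of 5.09, 4.48 and 4.15. The 8 genes with the largest positive differences were Cd4, the co-receptor of helper T cells, at 8.09 against 1.89, Il7r, Cd53 at 8.82 against 3.02, Msn at 8.03 against 2.23, Ptprc, the red cell genes Slc4a1 at 7.93 against 2.32 and Slc25a37 at 10.27 against 4.82, and Cd3e at 9.17 against 3.72. Several of these lay near or below the median of 2.18 on the array labelled lamina propria T cells, so the low end of that array may limit the sizes and order of these differences.

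Cytotoxic granule genes had a median difference of 0.80, with 8 of 13 members above the floor at least 2-fold higher and 1 lower, and tissue residency genes 1.19, with 9 of 14 higher and 1 lower. Cathepsin W (Ctsw) was higher by 4.14 and the chemokine Xcl1 by 4.14, whereas Bhlhe40 was lower, at 4.61 against 7.19. Itgae, the integrin that binds E-cadherin on epithelium, was at 4.82 against 2.33, Gzmb at 4.64 against 2.13, and Foxp3, the transcription factor of regulatory T cells, was at 3.90, a difference of 1.91. The gut homing receptor Ccr9 and the cytokine Il6 were below the level floor, at 1.81 against 1.83 and 1.44 against 1.25. Markers of other cell types were also higher in colon IEL: stromal markers by a median of 2.04, with Col1a1 at 7.59 against 3.60, B cell markers by 1.36 and MHC class II genes by 1.39. With the recolonized array in place of the colon IEL array, a choice made after seeing the data, the latter medians were smaller, at 0.56 for B cell markers and 0.82 for MHC class II genes. The list medians of this comparison given so far kept their sign under quantile normalization, centring and the lowess correction.

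All 15 pan-epithelial markers were at least 2-fold lower in colon IEL, with a median difference of −4.26, and the colonocyte markers had a median of −4.25, with 10 of 13 members lower and 1 higher. The largest differences were those of Cyp2c55 with −8.01, Reg4 with −7.44, the chloride and bicarbonate exchanger Slc26a3 with −7.44, Clca3b with −7.28 and the amino acid transporter Slc6a14 with −7.18. They were followed by B4galnt2 with −7.06, the gut hormone guanylin (Guca2a) with −6.85 and Ugt2b34 with −6.84; the other probe set of Cyp2c55 gave −0.62. Epcam was at 4.28 against 9.20. Goblet cell markers had a median difference of −2.55, oxidative phosphorylation genes −2.72 with 20 of 21 members at least 2-fold lower, and immediate early genes −2.69 with 14 of 18 lower, led by Jun at 3.04 against 8.97. After the lowess correction these 3 medians were −1.30, −1.49 and −1.52. Of 12789 genes above the floor, 1344 were at least 2-fold higher in colon IEL and 4437 lower, and their median difference was −0.44. Higher genes made up 23.2% of these, but 48.9% under quantile normalization, 47.6% after centring on the median and 44.2% after the lowess correction; these scalings draw the balance towards equal shares by their construction, so they do not show whether the excess of lower genes arose from the scaling. The spread within the comparison was an SD of 0.57 over ribosomal protein genes, 1.05 over reference genes and 1.75 between probe sets of the same gene. Reference genes had a median of −0.65 (94.6th percentile), with 4 of 12 at least 2-fold lower and 0 higher.

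Colon IEL and small intestinal IEL were compared to ask how IEL differ along the gut. The colon IEL array had higher levels of genes of naive and recirculating T cells and of Cd4, and lower medians of the cytotoxic granule and natural IEL lists. It also had higher stromal markers, and whether all of its T cells came from the epithelium was not tested. The naive and recirculation genes had a median difference of 1.12, above all 10000 random lists, with 8 of 13 members at least 2-fold higher; it was 2.11 under quantile normalization and 1.97 after the lowess correction. Lef1 was at 7.14 against 3.85, the lymph node homing receptor Ccr7 at 5.88 against 3.55, Il6ra at 5.76 against 3.43 and the chromatin organizer Satb1 at 5.74 against 3.78. The co-receptor and helper genes had a median difference of 0.45 (99.94th percentile), with 3 of 11 members at least 2-fold higher, namely Cd4 at 8.09 against 5.91, Cd5 and Cd27; this median was 1.17 under quantile normalization, 0.74 after centring and 1.01 after the lowess correction. The cytotoxic granule genes had a median difference of −1.38 (0.18th percentile), with 9 of 14 members at least 2-fold lower. They included Gzma at 4.98 against 10.38, Gzmb at 4.64 against 9.46 and Gzmk at 2.56 against 5.56, whereas Gzmc and Gzmm, chosen after their values were seen, differed by −0.14 and −0.19.

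The natural IEL genes had a median difference of −1.33 (0.79th percentile), with 9 of 14 members at least 2-fold lower: the inhibitory receptor Lag3 with −2.52, Fcer1g with −2.31, Cd8a with −2.02 and Cd244a with −1.96. Cd8b1, the partner chain of Cd8a in conventional CD8 T cells, was at 6.28 against 5.71. Itgae was at 4.82 against 7.90, Itga1 at 4.33 against 7.04 and Ccr9 at 1.81 against 3.24. The lists that hold these genes lay inside the range of random lists: tissue residency genes had a median of −0.68 (67.3rd percentile), with 7 of 14 members at least 2-fold lower and 0 higher, and gut homing and chemokine receptor genes −0.22 (36.4th percentile), which turned to 0.07 after centring, with 5 of 11 members above the floor lower and 0 higher. Other members leaned the other way by less than 2-fold, such as Itga4 with 0.46 and Cd69 with 0.35, both chosen after their values were seen. Foxp3 was at 3.90 against 2.66 and Il6 was below the floor on both arrays. The T cell receptor signalling genes differed by a median of −0.31 (95.95th percentile), and 12 of 14 were within 2-fold. This median was 0.68 under quantile normalization, 0.51 after the lowess correction and 0.74 with the recolonized array. In that last case the list lay above all random lists, with 5 of 14 members at least 2-fold higher and 0 lower. With the recolonized array in place of the colon IEL array, a choice made after seeing the data, the natural IEL list moved to −0.64 (10.9th percentile) and the cytotoxic list to −0.64 (7.47th percentile), both inside the range of random lists. The naive list was then at 1.59 and the helper list at 1.00, above all random lists.

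The list medians farthest from 0 in this comparison were those of epithelial and B cell genes. All 16 small intestinal enterocyte markers were at least 2-fold lower on the colon IEL array, with a median of −6.20, and so were all 8 Paneth cell markers, with a median of −6.44. On the colon IEL array these lists had median levels of 2.25 and 2.48, near the array's median of 2.41, so the sizes of these differences, and the order of single genes within them, may be limited by the low end of the array. The latter were led by Defa22, Defa24 and Defa21 with differences of −8.87, −8.04 and −7.32. Reg1 with −8.04, the peptidase Anpep with −7.88, Mgam with −7.63, the brush border enzyme sucrase-isomaltase (Sis) with −7.63 and the lipoprotein Apob with −7.35 were also among the largest. B cell markers had a median of −2.17 (−3.49 with the recolonized array), with 12 of 13 lower, among them Ms4a1, the B cell surface protein CD20, at 3.17 against 6.65. The immunoglobulin joining chain Jchain was at 2.21 against 7.64, and 17 of 17 immunoglobulin gene segments above the floor were at least 2-fold lower. Oxidative phosphorylation genes had a median of −1.93, with 18 of 21 lower; this median was −0.78 under quantile normalization and −0.97 after the lowess correction. Stromal markers were higher, with a median of 1.49 and Col1a1 at 7.59 against 4.18. The largest positive differences were those of Car1 with 6.01 and of genes that were also higher on the colon IEL array than on the recolonized array: Slc4a1 with 5.29, Rsad2 with 5.11, Fam220a with 4.93, Ube2o with 4.56, Fech with 4.48, the mitochondrial iron importer Slc25a37 with 4.47 and Isg20 with 4.19.

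Of 12553 genes above the floor, 751 were at least 2-fold higher in colon IEL and 3059 lower, with a median difference of −0.30. Higher genes made up 19.7% of these, but 49.6% under quantile normalization, 42.1% after centring and 39.7% after the lowess correction. Among genes under the median level of the array labelled lamina propria T cells, a subset chosen after seeing the data that leaves out genes bright on the epithelium-rich array, 347 were higher and 193 lower. The subset also changes the range of levels compared. The 25th percentile of gene levels was 1.84 on the colon IEL array and 1.64 on the small intestinal IEL array. Why the balance turned was not tested. The cytotoxic list kept its sign under every scaling with medians between −1.38 and −0.45, and the natural IEL list did so with medians between −1.33 and −0.42. The spread within the comparison was an SD of 0.56 over ribosomal protein genes, 0.83 over reference genes and 1.32 between probe sets of the same gene. Reference genes had a median of −0.80 (64.9th percentile), with 5 of 12 at least 2-fold lower and 0 higher.

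**Figure D3:**
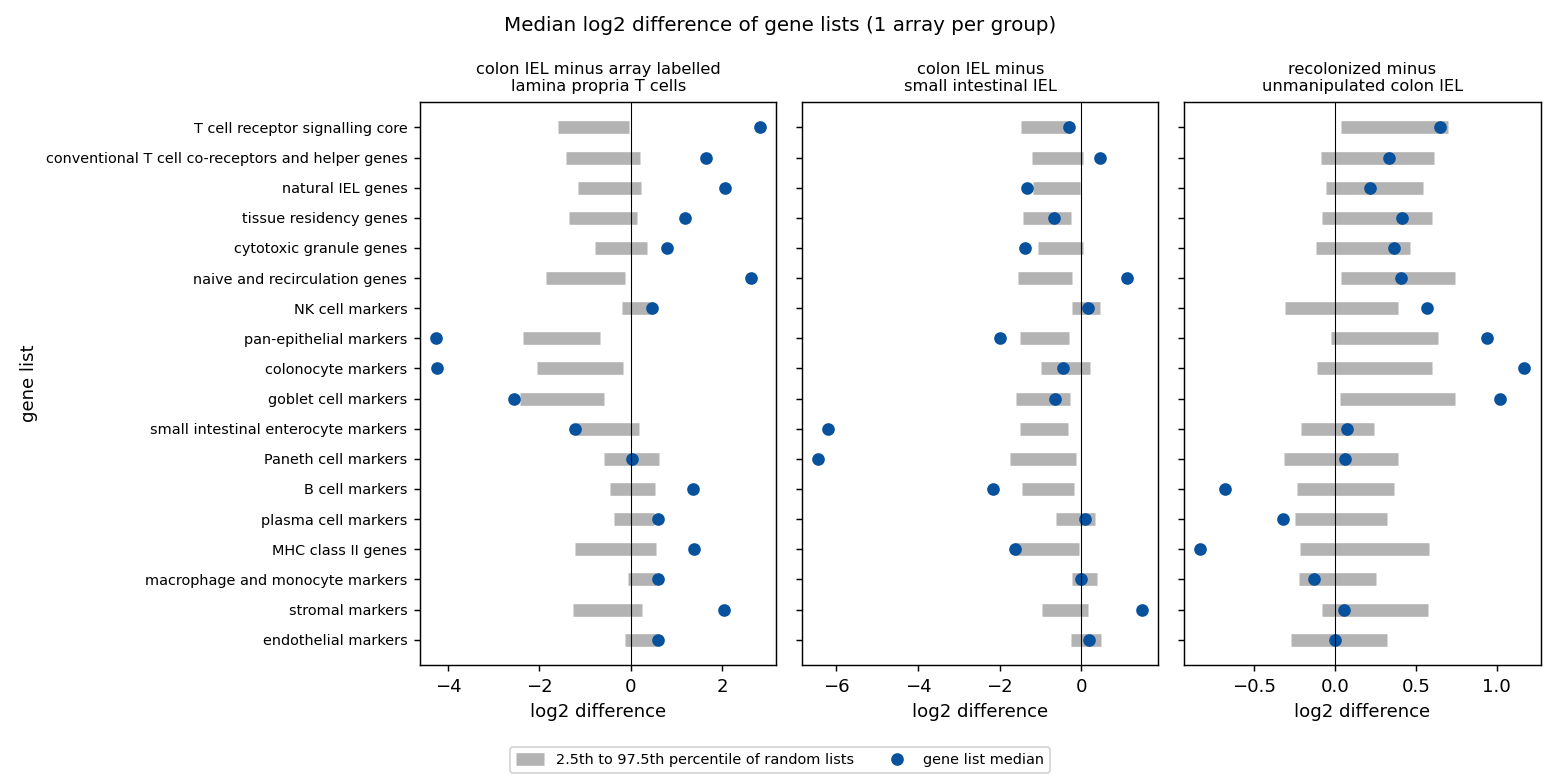
Median log2 difference (points, horizontal axes) of 18 gene lists in the 3 comparisons, with bars from the 2.5th to the 97.5th percentile of 10000 random lists matched on mean level. Naive and recirculation genes are at 1.12 and cytotoxic granule genes at −1.38 in colon against small intestinal IEL, and the T cell receptor signalling median of −0.31 in that panel becomes 0.68 under quantile normalization and 0.51 after lowess; colonocyte markers are at 1.17 and MHC class II genes at −0.83 in recolonized against unmanipulated colon IEL.

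Recolonized and unmanipulated colon IEL were compared to ask how antibiotics followed by return of the microbiota bear on colon IEL. No array came from mice given antibiotics alone, so the antibiotics and the return of bacteria cannot be told apart. Most T cell lists differed by no more than random lists did, while colonic epithelial genes and a few natural killer cell genes were higher on the recolonized array, and B cell and MHC class II genes were lower. The natural IEL genes had a median difference of 0.22 (43.9th percentile) with 13 of 14 members within 2-fold, and the sign of this median flipped under quantile normalization and the lowess correction. The tissue residency genes had a median of 0.41 (83.2nd percentile) with all 14 members within 2-fold. The regulatory T cell genes had 0.11 (71.3rd percentile), which turned to −0.02 after centring, with all 8 members above the floor within 2-fold. The cytotoxic granule genes had 0.36 (90.3rd percentile) with 3 of 15 at least 2-fold higher. Those 3 were Gzma at 7.73 against 4.98, the receptor Klrg1 at 3.45 against 2.01 and perforin (Prf1) at 5.24 against 4.17.

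The natural killer cell markers had a median difference of 0.57 (99.78th percentile), with 3 of 7 members at least 2-fold higher, namely Gzma, Klrg1 and Ncr1, and 1 lower, Fcgr3. T cell receptor signalling genes differed by a median of 0.65 (95.36th percentile), with Bcl11b and Lat at least 2-fold higher; this median was 0.27 under quantile normalization and 0.18 after the lowess correction. Of the genes named in any case, Cd8a was at 7.04 against 6.48, Cd8b1 at 7.52 against 6.28, Cd4 at 7.70 against 8.09, Itgae at 5.47 against 4.82, Foxp3 at 4.90 against 3.90 and Gzmb at 4.76 against 4.64. Il6, Ccr9 and Jchain were below the level floor on both arrays, with Il6 at 1.12 against 1.44. Of 43 lists with enough members, 4 lay above the range of random lists and 3 below it. The natural killer list among these 7 holds genes that are also on T cell lists. It shares Gzma and Klrg1 with the cytotoxic granule list, Eomes with the Th1 and type 1 list and Klrk1 with the natural IEL list. Whether its difference came from T cells or natural killer cells was not tested. The other 6 were lists of epithelial, B cell, plasma cell and MHC class II genes. Th1 and type 1 genes lay just inside the range, with a median of 0.44 (97.24th percentile) and differences from 0.06 to 1.01 over 13 members. Their median was 0.28 under quantile normalization and 0.24 after the lowess correction.

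Colonocyte markers had a median difference of 1.17, above all 10000 random lists, with 8 of 13 members at least 2-fold higher, and goblet cell markers had 1.02 (99.96th percentile) with 6 of 12 higher. The pan-epithelial markers had 0.94 (99.97th percentile) with 7 of 15 higher, including Epcam at 5.91 against 4.28. The 8 largest positive differences were those of Ly6c2 with 3.79, a surface protein of monocytes and memory T cells, Car4 with 3.68, Guca2a with 3.47, Tma7 with 3.17, cytochrome c (Cycs) with 3.12, the goblet cell protein Fcgbp with 3.11, Tm4sf20 with 3.07 and Mptx1 with 3.01. The other probe sets of Tma7 and Cycs gave differences down to 0.66 and −0.81. MHC class II genes had a median of −0.83, below all random lists, with 4 of 8 members at least 2-fold lower and H2-Ab1 at 4.31 against 7.62. B cell markers had a median of −0.68, also below all random lists, with 6 of 11 lower, among them the antigen receptor chains Cd79a and Cd79b with −2.26 and −1.92. Plasma cell markers had −0.32 (0.84th percentile) with 1 of 8 lower. The largest negative differences were those of Slc25a37 with −5.85, Slc4a1 with −5.61, Fech with −5.03, Rsad2 with −4.95, Bpgm with −4.56, Fam220a with −4.56, Isg20 with −4.42 and Ube2l6 with −4.39. Slc25a37, Slc4a1, Fech and Bpgm among them are genes of red cells. Slc4a1 was at 2.32 on the recolonized array, under that array's median gene level of 2.39, so the low end of the array may limit the size and rank of its difference. The red cell and platelet list fixed before the data were examined had 3 members measured, all of them platelet genes, with a median of 0.11 and, of the 2 above the floor, 1 at least 2-fold higher (Ppbp with 2.19) and 0 lower. The interferon-stimulated genes as a list had a median of 0.00 (−0.14 under quantile normalization), with 2 of 14 members at least 2-fold lower, Rsad2 and Isg15.

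Of 12443 genes above the floor, 751 were at least 2-fold higher in recolonized colon IEL and 381 lower, with a median difference of 0.13. Higher genes made up 66.3% of these, but 48.8% under quantile normalization, 48.2% after centring and 46.6% after the lowess correction. Among genes under the median level of the array labelled lamina propria T cells, 67 were higher and 140 lower. The colonocyte, goblet, pan-epithelial, natural killer, B cell, plasma cell and MHC class II medians kept their sign under each of these scalings. The spread within the comparison was an SD of 0.58 over ribosomal protein genes, 0.62 over reference genes and 0.86 between probe sets of the same gene. Reference genes had a median of 0.39 (49.9th percentile), with 1 of 12 at least 2-fold higher and 0 lower. Neither array of the comparison could be replaced.

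Across the 6 pairs of arrays, the 2 colon IEL arrays were the closest, with 1132 of 12443 genes at least 2-fold apart and a Pearson correlation across genes of 0.880. The recolonized array and the small intestinal IEL array differed by 2-fold in 2808 genes, and the unmanipulated colon IEL array and the small intestinal IEL array in 3810. The array labelled lamina propria T cells differed in 2975 genes from small intestinal IEL, in 4994 from recolonized colon IEL and in 5781 from colon IEL. The difference between recolonized and unmanipulated colon IEL shares no array with the difference between small intestinal IEL and the array labelled lamina propria T cells. Over 14018 genes these correlated with r = −0.082 and rho = −0.080 across genes, which are not independent replicates.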

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

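The alternatives fixed in advance were run 1 at a time; use of the recolonized array in place of the unmanipulated one and the restriction to genes under the median of the array labelled lamina propria T cells were chosen after seeing the data. A level floor at the 25th percentile, no floor and the mean of probe sets left all 6 counts within 1.5 times. So did the recolonized array, in the 4 counts where it was used. The counts are given as higher and lower, for colon IEL against the array labelled lamina propria T cells, then against small intestinal IEL, then for recolonized against unmanipulated colon IEL. A looser or stricter threshold moves a count by its construction: at 1.5-fold, 2750 higher in the first, 2024 and 4785 in the second, 2402 and 1298 in the third; at 3-fold, 493 and 2789, 163 and 1569, 146 and 109. With the floor at the 75th percentile, 486 genes were higher in the second. Quantile normalization gave 2287 and 2387, then 1650 and 1674, then 874 lower in the third. Centring gave 2846 higher in the first and 1601 in the second. The lowess correction gave 2356 lower in the first, 1653 lower in the second and 437 higher in the third. These scalings draw the balance of higher and lower genes towards equal by their construction; whether the balance without them is an effect of scaling was not tested. Genes under the median of the array labelled lamina propria T cells gave 347 and 193 in the second and 67 and 140 in the third, from fewer genes and another range of levels. Of the 6 pairs of arrays, the count of genes 2-fold apart moved by over 1.5 times for the colon IEL pair alone, to 1708 under quantile normalization. The correlation of differences that share no array stayed between −0.096 and −0.081.

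Of the list medians called outside the range of random lists, the sign of 1 turned: cytosolic ribosomal protein genes in colon IEL against the array labelled lamina propria T cells, at −0.04, were at 0.99 under quantile normalization, 0.40 after centring, 0.99 after lowess and 0.23 with the recolonized array; the cause was not tested. Over all lists, 587 alternative medians stayed within the width of chance and 140 moved beyond it without such a reversal. For single named genes, 234 alternative differences stayed within 1.5-fold of the reported value and 74 did not, and no difference of 2-fold or more turned its sign. Leaving out a replicate and a paired analysis were not possible with 1 array per group. Signal over background could not be assessed, since background values are not used here, and the narrow range of the colon IEL arrays limits how far small differences of dim genes can be read.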

Other observations

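All tests of explanations below were chosen after the patterns had been seen. The rules of all but 2 of them (the narrower range for the Y-linked genes, and red cell RNA) were revised after a first version had been run. Oxidative phosphorylation genes had median levels of 7.69 on the array labelled lamina propria T cells, 7.04 on small intestinal IEL, 4.33 on colon IEL and 5.37 on recolonized colon IEL. In recolonized against unmanipulated colon IEL their median difference of 0.47 (89.9th percentile) lay inside the range of random lists. Glycolysis genes lay inside that range in all 3 comparisons, at the 13.3rd percentile for colon IEL against the array labelled lamina propria T cells, the 6.59th for colon against small intestinal IEL and the 70.6th for recolonized against unmanipulated colon IEL. Genes of lipid uptake and oxidation had a median difference of −2.47 (0.02nd percentile) in the first comparison, −1.13 (0.96th percentile) in the second and 0.22 (84.1st percentile) in the third. Under quantile normalization these medians were −1.23, −0.295 and 0.16, and after the lowess correction −1.20, −0.43 and 0.135. Immediate early genes were at the 60.6th percentile in the second, with a median of −0.43. In the third, the immediate early genes Btg2, Zfp36 and Klf6 were higher by 2.10, 1.89 and 1.66, while the list median of 0.42 lay at the 96.3rd percentile. The fatty acid transporter Cd36 was lower on the recolonized array, at 1.85 against 3.53.

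Of genes by which epithelium acts on microbes and IEL, the antimicrobial Reg3g was at 8.83 on the small intestinal IEL array and 2.70 on the colon IEL array, and the butyrophilin-like Btnl1 at 6.57 and 2.04. The lists they belong to lay inside the range of random lists in this comparison: antimicrobial genes had a median difference of 0.07 (40.8th percentile; −0.06 under quantile normalization and −0.12 after lowess) and butyrophilin-like genes −0.93 (2.66th percentile). Between recolonized and unmanipulated colon IEL, the antimicrobial genes Retnlb and Ang4 were higher by 2.60 and 2.42 and Lyz1 lower, with −2.32, while the list had a median of −0.15 (5.62nd percentile). With the recolonized array set against small intestinal IEL, B cell markers had a median of −3.49 and MHC class II genes −2.26. Colonocyte markers were then higher by 0.71, above all random lists, whereas with the unmanipulated colon IEL array their median was −0.46 (34.4th percentile; 0.13 under quantile normalization and 0.06 after lowess).

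The array labelled lamina propria T cells carried colonic epithelial transcripts and little T cell signal. T cells with some epithelial carry-over, if they made up most of the sample, would keep T cell genes within 2-fold of the IEL arrays. Against the mean of the 3 IEL arrays, 11 T cell receptor signalling genes that reached a log2 level of 5 on any array were lower. Their median difference was −3.85 (SD 1.59 over genes), from −1.19 for Bcl11b to −6.07 for Cd3g. Several of them lie near the low end of this array, so the differences may be larger than printed. No gene of the list exceeded 3.75 on this array, so all 11 passed the level rule through the IEL arrays. Over all 14 measured members, the median was lower on this array by 2.83 against colon IEL and 3.73 against recolonized colon IEL. The list had shown the pattern in the first place, so these values restate it and are no separate support. The test of a lamina propria digest in which T cell enrichment failed cannot decide. Of 7 lists of stromal, endothelial, B, plasma, macrophage, dendritic and granulocyte genes, 29 genes reached a log2 level of 5 on any array. Their median difference from the mean of the 3 IEL arrays was −2.13 (SD 1.42 over genes), with 26 at least 2-fold lower and 1 higher. From single arrays it was −3.28 (SD 2.02) for small intestinal, −2.13 (SD 1.80) for colon and −1.12 (SD 1.78) for recolonized colon IEL, the last within the spread of the genes. Genes could pass the level rule through the IEL arrays they were then compared with, which favours a negative median. Over all measured members, each of the 7 list medians was higher on the colon IEL array, by 0.51 for dendritic to 2.04 for stromal markers. Colonic epithelial cells hybridised under this label remain a candidate explanation. Colonocyte markers were higher than on each IEL array by a median of at least 3.20 and goblet cell markers by at least 1.53. These lists had shown the pattern in the first place, so their values restate it and are no separate support. Paneth cell markers differed by −6.55 from small intestinal IEL and by −0.02 and −0.12 from the colon IEL arrays. The labels name an antibody against EpCAM in the enrichment, a step meant to remove such cells, although the small intestinal IEL array, described with the same step, had pan-epithelial markers at a median level of 6.98. Whether another tube or the bound fraction was hybridised was not tested, and no biological explanation was tested.

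Sex-linked genes split the arrays, although the labels name an equal pool of males and females. Whether that pool was per array or over the series is left open by the labels. Pools with unequal shares of males and females remain a candidate explanation. Between the array with the highest Xist (recolonized colon IEL) and the array with the lowest (labelled lamina propria T cells), Xist differed by 4.08 and the 3 Y-linked genes by a median of −2.99. Xist and all 3 Y-linked genes were at least 2-fold apart in opposite directions in 2 of the 6 pairs of arrays. In colon IEL against small intestinal IEL both were lower, which unequal shares alone would not give: Xist differed by −1.61 (−0.55 under quantile normalization and −0.69 after lowess) and the Y-linked genes by a median of −1.36. In recolonized colon IEL, Xist and the Y-linked median differed by 0.25 and −1.70 from small intestinal IEL and by 1.86 and −0.46 from colon IEL. Xist on the array labelled lamina propria T cells, at 1.86, lay under that array's median gene level of 2.18. The 3 Y-linked genes on the recolonized array lay under its median of 2.39. Both opposite pairs include the array labelled lamina propria T cells, so a difference between cell types in these genes stays open and untested, and so does whether any pool held 1 sex. The narrower range of the colon IEL arrays is argued against as the cause of their low Y-linked levels, since the median difference of −1.53 from small intestinal IEL lay at the 0.13th percentile of 10000 random triples matched on level. Levels of sex-linked genes therefore differed within each of the 3 comparisons.

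Red cell genes stood high on the colon IEL array of unmanipulated mice. A list of 28 red cell genes was written after the pattern had been seen; of 25 measured, 20 were higher on this array than on the recolonized array, 9 of them at least 2-fold, with a median difference of 0.85 (SD 2.01 over genes) and of 0.81 after the lowess correction. These include the 5 genes that prompted the list (Slc4a1, Slc25a37, Fech, Bpgm and Ube2o). Of the other 20, 15 were higher and 4 of these at least 2-fold, with a median of 0.295 (SD 0.94). The red cell and platelet list fixed before the data were examined had 3 platelet genes measured and did not show this. Globin genes share 5 probe sets that list several symbols, which were left out of the comparisons. Their median level was 10.20 on the colon IEL array, 5.79 on the recolonized array and 5.29 on the small intestinal IEL array. It was 1.90 on the array labelled lamina propria T cells, so globin signal was not confined to the colon IEL array. The narrower range of the colon IEL array is argued against, since after the lowess correction the median difference of these probe sets was 3.49 (SD 1.47), against an upper bound of 0.77 for 10000 random sets of probe sets matched on level. Red cell RNA in this sample remains a candidate explanation: before correction the 5 probe sets were higher by 1.69 to 5.01, with a median of 3.35, and Slc25a37 and Fech were at 10.27 and 9.56. The labels describe magnetic negative selection for T cells, a step meant to remove other cells, and whether it covered red cells was not tested. An interferon response across the list is argued against as the cause: the median of the 16 interferon-stimulated genes was −0.004 (SD 1.44), against 3.35 for the globin probe sets. The bound set for this test was Isg15 with 2.56, which belongs to the same list, so the median's place below it adds no separate support. Of the 16, 14 lay between −0.95 and 0.34, and Rsad2 was higher by 4.95. Isg20 and Ube2l6, which are not on the list, were also among the genes with the largest differences between these arrays. Why Rsad2, Isg15, Isg20 and Ube2l6 stood high was not tested. The treatment, which differs between these arrays, stays open and untested.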
